A study of Drosophila melanogaster with 4 samples.

How the data were processed

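RNA from mature adult males of 2 Drosophila melanogaster strains was compared on Agilent 2-colour oligonucleotide arrays. 91R is the DDT-resistant strain and 91C the control strain it was compared with, per the labels. Each of the 4 arrays carried both strains, with the 91R sample labelled with Cy5 (red) and the 91C sample with Cy3 (green) on all 4. Per the labels' protocols, total RNA was extracted with an organic reagent, cleaned on columns, amplified from the polyadenylated fraction into dye-labelled cRNA and mixed with Agilent's spike-in controls. No array had the dyes swapped, so a difference between the strains and a difference between the dyes have the same sign on every array. The labels number the arrays as replicates 1 to 4 and do not say whether they hold separate RNA extracts, or whether the 91C RNA was a single pool. The p-values therefore measure only the spread between these 4 hybridisations, which may be technical. All 4 arrays lay on 1 slide with 1 scan, so there was no batch to test.

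The authors deposited one scanner file per array and a table of processed values. Per the file headers, the spot intensity values are mean pixel brightness and median local background of each channel, extracted with Agilent Feature Extraction 10.5.1.1, while the submitters' processing notes name version 9.5.1.1. Per the file headers, the software also gives processed signals, which are background-subtracted and dye-normalized, and a log10 ratio of red over green, which was not used in any test. The deposited value table is a log2 ratio whose scale, centring and direction were found from the data. On each array its values correlated at 1 with the log2 ratio of the same array's processed signals, red over green, with a slope of 1, and at no more than 0.854 with those of any other array. Its columns had medians of 0.0292, 0.0232, 0.0171 and 0.0187 for replicates 1 to 4, and 275, 0, 1 and 3 values were missing. It holds 91R over 91C, the direction used here. It carries no centring beyond the dye normalization of Feature Extraction, so none of scale, centring and direction stays unknown.

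Mean signals were corrected with normexp (offset 50) against the local background and normalized by loess within each array, with control spots and outlier-flagged spots at weight 0. Control spots (1417 per array, beside 43603 other spots) and flagged ones among the other spots (786, 128, 55 and 103 on replicates 1 to 4) were then left out. None of the other spots was saturated. Spots of one probe were averaged, giving 32162 probes of 60 bases. A probe was kept if it was well above background in the same channel on at least 3 of the 4 arrays, which left 26427 probes. Gene names came from the files' own annotation, updated through a RefSeq gene table of Release 6 by locus tag (19816 probes), synonym (672), accession (234) or symbol (25), and the files' name was kept for 193 probes. In all, 20940 probes named 13334 genes, 13178 of them in the table, and 11222 probes named only an EST, a cluster or nothing and entered only the probe-level comparison. Each gene was represented by its kept probe of highest mean brightness. Coordinates are those of the probes in the files, on build dm3 (BDGP release 5) per the file headers.

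The mean log2 ratio of 91R over 91C was fitted as an intercept with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), tested two-sided against 0 and adjusted by Benjamini-Hochberg over the 12560 genes measured, or over the 26427 probes. A gene was called at an adjusted p of at most 0.05, and a second count asked for a ratio of at least 2-fold. Of 31 gene lists fixed by symbol, 29 had at least 5 measured genes and were tested with camera at a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. A gene whose chosen probe was not well above background in one strain on all 4 arrays has only a bound. It is given as at least N-fold, from channel values after loess and Aquantile, the dim side being the higher of the probe's own value and the lowest signal well above background. For each gene named with a bound, it equalled the fold of the mean log2 ratio over the arrays, so a single array can lie below it. Such bounds are open to dye bias. The normexp offset pulls the ratios of dim probes towards 0.

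The genes named were chosen by a rule: the 12 highest and the 12 lowest log2 ratios among called genes with the same sign on all 4 arrays, the 3 members of each list with the smallest p, and 18 genes with known roles in insecticide metabolism, transport or action. Genes named outside it are marked as chosen after their values were seen. The design, the gene lists, this rule and the alternatives were fixed before the data were examined, except an adjustment for the base composition of the probes, added afterwards. The alternatives were other background corrections, Agilent's processed signals, median centring in place of loess, a separate-channel fit, the deposited value table, other filters on dim probes, the mean of a gene's probes, a trended robust prior, array weights and leaving out each array.

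The procedure was tested on simulated data with the observed spread for 12388 genes. At log2 ratios of 0.25, 0.5, 1 and 2, it recovered 56%, 90%, 96% and 100% of 50 changed genes each, and 4.47% of its calls were false. Far fewer genes were changed there than were called in the data, and the simulated noise held no dye or probe effect. These rates therefore do not carry over to the genes called in the data. Chromosome arms and symbol families were tested with Fisher's exact test, and neighbouring genes and proteasome copies with permutation tests. Figures were drawn with matplotlib 3.10.9, and annotation was joined with pandas 2.3.3 under Python 3.11.15.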

Results

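The data were 4 arrays, each a direct comparison of 91R, a DDT-resistant strain of Drosophila melanogaster, with the control strain 91C. The series was made to find genes expressed differently in the resistant strain. Flies were mature adult males, and all ratios are given as 91R over 91C. Median spot brightness was 386.9, 424, 533.9 and 515.1 in the red (91R) channel of replicates 1 to 4, against local backgrounds of 48.5 to 51.5. In the green (91C) channel it was 181.8, 197.4, 211.1 and 229.6, against backgrounds of 16 to 17.5. Between 74.36% and 77.32% of the probes were well above background in red and between 81.18% and 83.21% in green. Log2 ratios correlated at 0.902 to 0.925 between arrays across the kept probes, which are not independent replicates. The spike-in RNAs, mixed at known ratios, gave slopes of 0.908 to 0.919 of observed on expected log ratios, per the file headers. The number of arrays, 4, limits the precision of each value.

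Cytochrome P450 genes were among the largest differences between the strains. Cyp6a2 had the highest ratio of all genes called in the main processing, at a log2 ratio of 6.49 ± 0.16 (SD, n = 4), or 89.7-fold. With Agilent's processed signals it was at 7.38, below CG11756 (8.46), CG15293 (8.16) and CG42847 (7.91) among others, and with a normexp offset of 0 CG15293 also exceeded it. The other genes far above 91C included Cyp6a8 (41.5-fold), Cyp4p1 (21.7-fold) and Cyp6g1, a P450 known for its overexpression in DDT-resistant field strains (9.96-fold). At the other end, CG8708 was 75.3-fold lower in 91R, at -6.23 ± 0.51 (SD, n = 4). Of 12560 genes measured, limma called 8703 (69.3%), 4166 higher and 4537 lower in 91R. Most of these differences were small, with a median absolute log2 ratio of 0.34, and 6704 of the 8703 were under 1.5-fold. At least 2-fold differences were called for 709 genes (5.64%), 367 higher and 342 lower, and 703 of them had the same sign on all 4 arrays. At least 8-fold differences were found for 38 genes higher and 23 lower in 91R. With median centring in place of loess the split of all calls moved to 4905 higher and 3549 lower. With Agilent's processed signals, or the deposited value table made from them, the 2-fold count was 1263, and the cause was not tested. No array had swapped dyes, so the counts include any gene whose ratio came from the dyes.

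**Figure D1:**
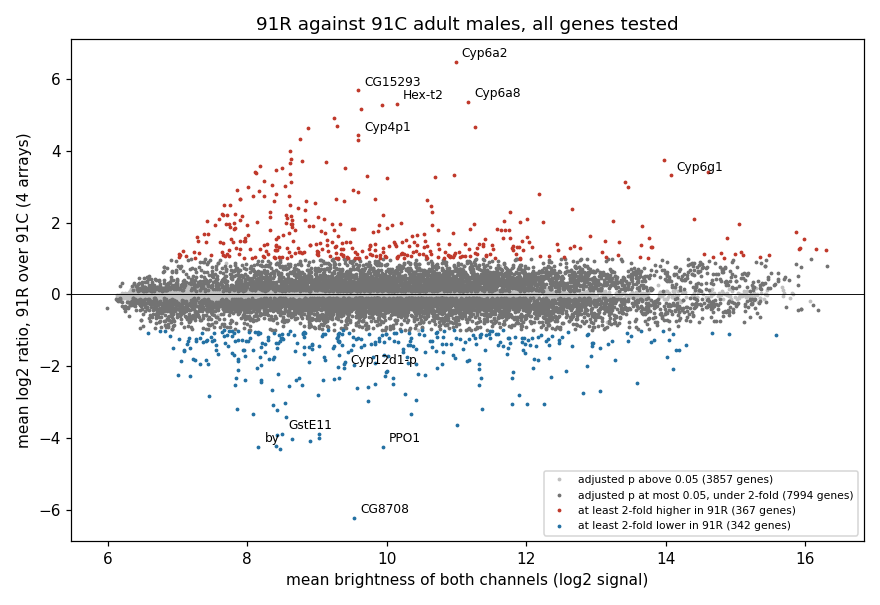
Mean log2 ratio of 91R over 91C (4 arrays) against the mean log2 brightness of both channels, 1 point per gene for 12560 genes. Red and blue points are the 367 genes called at least 2-fold higher and the 342 called at least 2-fold lower in 91R, and grey points are the other genes. Cyp6a2 lies at the top at 6.49 and CG8708 at the bottom at -6.23.

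Among 24 measured P450 genes linked to insecticide resistance, 12 were higher in 91R, 9 lower and 3 not called. Cyp6a2 (FBgn0000473, probe on chromosome 2R, 2667273 to 2667332), Cyp6a8 (FBgn0013772, 2R, 10774861 to 10774920) and Cyp6g1 (FBgn0025454, 2R, 8075583 to 8075642) are on the same chromosome arm. The log2 ratio was 5.37 ± 0.26 for Cyp6a8, 4.44 ± 0.06 for Cyp4p1, 3.32 ± 0.09 for Cyp6g1 and 2.99 ± 0.17 for Cyp6w1 (SD, n = 4 each). The adjusted p was 1.13e-07 for Cyp6a2, 5.22e-07 for Cyp6a8, 9.10e-08 for Cyp4p1 and 2.36e-07 for Cyp6g1, each higher in 91R on 4 of 4 arrays. Cyp4p2, next to Cyp4p1, was at least 6.37-fold higher, because its probe was not well above background in 91C on any array, and its other probe gave 0.56. Cyp6g2, the neighbour of Cyp6g1, was higher by 0.73 ± 0.18. Cyp12d1-d and Cyp12d1-p, near-identical copies that one probe may not tell apart, were lower at -2.21 ± 0.20 and -2.06 ± 0.08. Cyp4g1, which makes the hydrocarbons of the cuticle, was not called, with 0.21 ± 0.24 and an adjusted p of 0.0755. Its 3 probes gave 0.21, 0.02 and -1.32, and with the probes averaged on each array, 1 of them missing on replicate 1, the value was -0.44, past the threshold. In 4 of 16 other settings it was called higher in 91R, at up to 0.77 after median centring (adjusted p = 0.000426). Cpr, the reductase that supplies P450s with electrons, was at 0.07 ± 0.14 and not called, but was called higher in 2 of 16 other settings, at up to 0.52 after median centring (adjusted p = 0.000558). Over the whole P450 family, 21 of 80 measured genes were higher and 41 lower. Its median was -0.167 and its mean 0.0315, and neither the family (camera adjusted p = 0.167) nor the resistance-linked subset (median 0.208, or 0.43 after median centring, adjusted p = 0.468) shifted as a list, though the family passed after median centring, at -0.202.

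**Figure D2:**
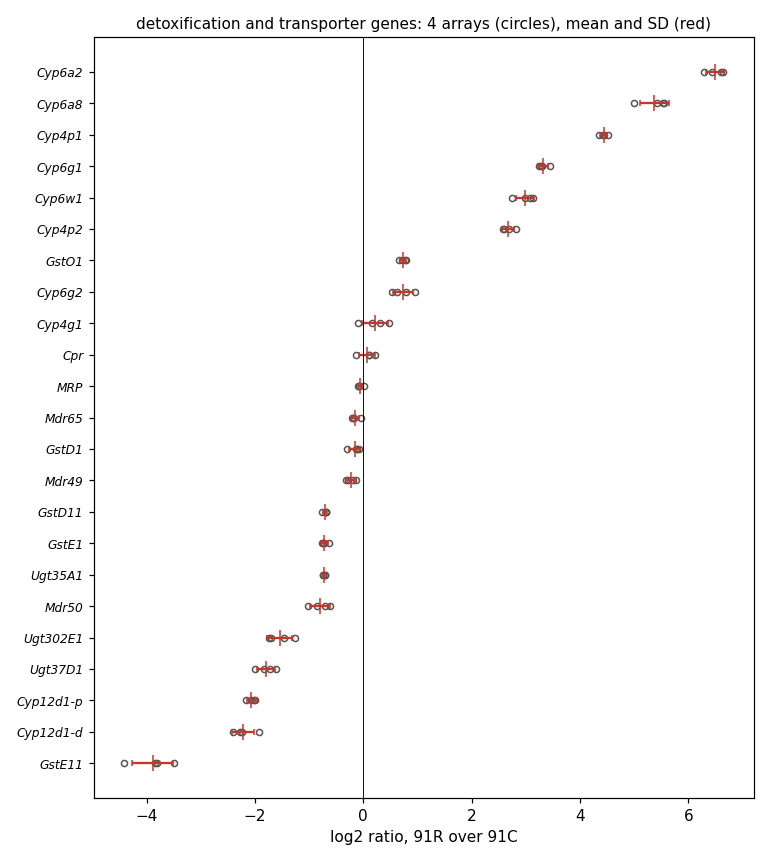
Log2 ratio of 91R over 91C on each of 4 arrays (circles), with the mean and SD (red), for 23 named detoxification and transporter genes. Cyp6a2 at 6.49 and Cyp6a8 at 5.37 lie farthest to the right and GstE11 at -3.89 farthest to the left. The probe shown for Cyp4p2 was not well above background in 91C, so its mean is given in the text as a bound.

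Other detoxification families held genes on both sides. Of 35 glutathione S-transferases, which join glutathione to foreign compounds, 10 were higher and 18 lower, or 11 and 18 adjusted over the list alone. GstE11 was 14.8-fold lower, at -3.89 ± 0.38 (SD, n = 4, adjusted p = 4.76e-06, well above background in 91R on 3 of 4 arrays), or at -6.68 with Agilent's processed signals, GstE1 was at -0.72 ± 0.06, GstD11 at -0.71 ± 0.03 and GstO1 at 0.73 ± 0.06. GstD1 was at -0.16 ± 0.10, and at 0.16 after median centring, and lost the threshold in 2 of 16 other settings (highest adjusted p = 0.0547). Of 34 UDP-glycosyltransferases, which join sugars to such compounds, 7 were higher and 21 lower, with Ugt37D1 at -1.79 ± 0.16, Ugt302E1 at -1.54 ± 0.23 and Ugt35A1 at -0.73 ± 0.02. As lists, neither the transferases of glutathione (median -0.157, or -0.0552 after median centring, camera adjusted p = 0.468) nor those of sugars (median -0.302, adjusted p = 0.0574) passed the threshold, but those of sugars did in 8 of 16 other settings (lowest adjusted p = 0.00678). Of 16 ABC transporters, 2 were higher and 10 lower (median -0.192, or -0.105 after median centring, adjusted p = 0.113). Mdr50 was at -0.80 ± 0.18, Mdr49 at -0.23 ± 0.08 and Mdr65 at -0.15 ± 0.08, and MRP, not called, at -0.06 ± 0.05. Mdr65 lost the threshold in 3 of 16 other settings (highest adjusted p = 0.0625) and Mdr49 after median centring (-0.08, adjusted p = 0.112), where MRP was called at 0.13. The pigment transporters bw and st were at -0.68 ± 0.14 and -0.59 ± 0.09, and a second probe of bw gave 0.08. Among 15 carboxylesterases, 6 were higher and 8 lower. Jhedup was at 2.67 ± 0.07, alpha-Est7 at -0.66 ± 0.06 and alpha-Est8 at -0.60 ± 0.07. The list median was -0.12, or 0.196 after median centring, and the adjusted p was 0.915. Of 23 antioxidant genes, 6 were higher and 10 lower, or 6 and 12 adjusted over the list alone, with Gclc at -1.06 ± 0.06, Prx1 at 0.57 ± 0.04 and Trxr2 at 0.54 ± 0.06. Their median was -0.136, or 0.173 after median centring, with an adjusted p of 0.776.

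The genes of neuronal ion channels and receptors include targets of DDT and other insecticides. Of 28 neuronal ion channel and receptor genes, 8 were higher, 9 lower and 11 not called, with a median of -0.01 (0.000845 after median centring) and none at least 2-fold apart. The sodium channel gene para, the target of DDT, was at 0.32 ± 0.10 (SD, n = 4, adjusted p = 0.000938), with other probes at 0.20 and -0.32, and the mean of its probes, 0.07, did not pass. The GABA receptor gene Rdl was at -0.24 ± 0.07 by its brightest probe, with other probes at -0.01, 0.00 and 0.07, and was not called with the mean of its probes (-0.05) or after median centring (-0.03). The other examples were sei at 0.68 ± 0.07 and nAChRalpha2 at -0.52 ± 0.06. Ace, which encodes acetylcholinesterase, was at 0.60 ± 0.05 by its brightest probe, and its other 3 probes gave -0.22, -0.03 and 0.00. An acetylcholinesterase mean over all probes of 0.09 was not called.

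Outside these families, the highest ratios included those of CG15293 (5.69 ± 0.13), Hex-t2 (5.32 ± 0.16), CG33109 (5.29 ± 0.21), CG31709 (5.18 ± 0.16), CG42847 (4.91 ± 0.20), CG9483 (4.69 ± 0.07), BomBc3 (4.67 ± 0.32) and CG11756 (4.34 ± 0.22), all SD with n = 4. Hex-t2 encodes a testis hexokinase and BomBc3 a peptide of the Bomanin immune family. CG31174 was at least 25.1-fold higher, with a probe not well above background in 91C. In the weaker channel CG11756 was well above background on 2 of 4 arrays, and with Agilent's processed signals it was at 8.46, CG15293 at 8.16 and CG42847 at 7.91. A second probe of CG33109 went the other way, at -0.71. Besides CG8708, the lowest included by (-4.25 ± 0.34), PPO1 (-4.24 ± 0.83), PH4alphaNE3 (-4.22 ± 0.39), CG31832 (-4.09 ± 0.25), CG3397 (-4.01 ± 0.48), CG9702 (-3.92 ± 0.16), CG11298 (-3.89 ± 0.42) and CG17010 (-3.63 ± 0.44). In 91R, by and CG9702 were well above background on 1 of 4 arrays each, and PH4alphaNE3 on 3. With Agilent's processed signals by was at -6.87, CG9702 at -7.22 and PH4alphaNE3 at -6.83. The gene by encodes tensin, and PPO1 a prophenoloxidase that forms melanin. CanA1, a calcineurin subunit, was at least 19.9-fold lower by the mean of its brightest probe (-3.78 on replicate 4) and at -2.36 by another. Kap3 was at least 16.4-fold lower by a probe not well above background in 91R, but at -0.15 by its other probe. For CG17010 the other probe gave 0.00, for CG3397 it gave -1.75 and for by -3.26.

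**Figure D3:**
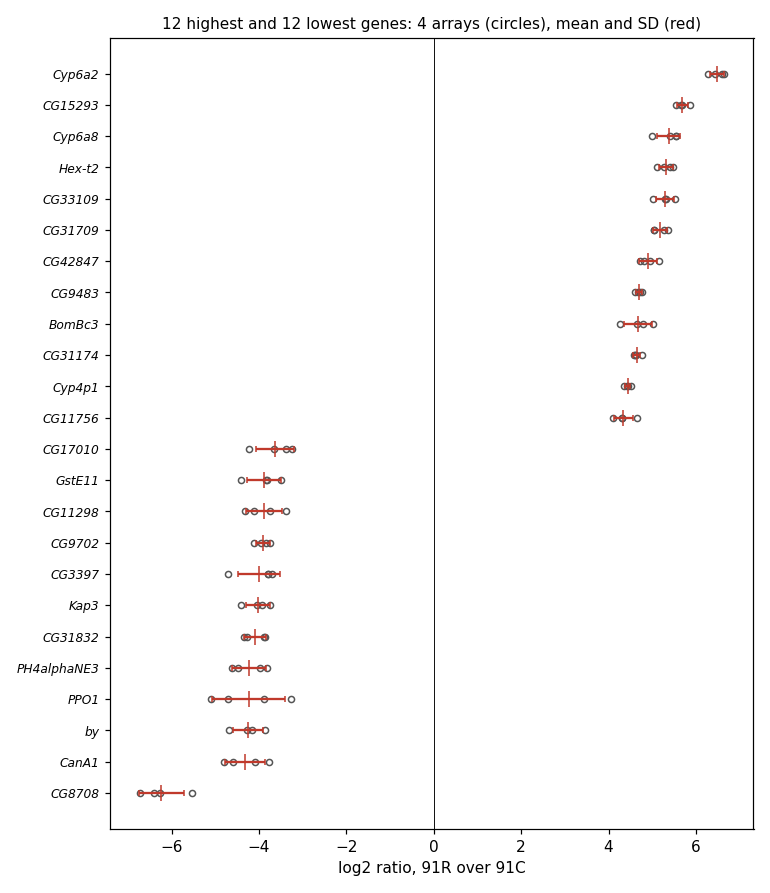
Log2 ratio of 91R over 91C on each of 4 arrays (circles), with the mean and SD (red), for the 12 highest and the 12 lowest genes among those called with the same sign on all 4 arrays. The means run from 6.49 for Cyp6a2 to 4.34 for CG11756, and from -3.63 for CG17010 to -6.23 for CG8708. Among the 24, PPO1 has the widest spread (SD 0.83). The probes shown for CG31174 in 91C and for CanA1 and Kap3 in 91R were not well above background, so their means are given in the text as bounds.

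Testis genes were higher and blood cell genes lower in 91R. Of 38 testis and sperm genes, 33 were higher, 2 lower and 3 not called, with a median log2 ratio of 0.576 (0.534 to 0.602 over the 4 arrays, 0.953 after median centring, camera adjusted p = 1.34e-07, and adjusted p = 0.906 with an estimated correlation). Mst89B was at 1.81 ± 0.07, loopin-1 at 1.18 ± 0.12 and Mst98Ca at 1.09 ± 0.06. Of 20 haemocyte genes, 1 was higher and 17 lower, with a median of -0.669 (-0.788 to -0.504 over the arrays, camera adjusted p = 0.00092, and adjusted p = 0.906 with an estimated correlation). PPO2 was at -2.33 ± 0.40, Hml, a clotting protein made by haemocytes, at -1.95 ± 0.15 and NimC2 at -1.37 ± 0.12, and other probes of Hml gave -1.04 and 0.13. Both medians kept their sign under every scaling tried. With an estimated correlation between genes no other list passed either. Of 97 oxidative phosphorylation genes, 19 were higher and 60 lower, with a median of -0.319 (camera adjusted p = 0.0346, and adjusted p = 0.906 with an estimated correlation). The mitochondrial genes ND5 and ND1 were at -1.55 ± 0.13 and -1.54 ± 0.10, and the nuclear gene ND-AGGG at 2.08 ± 0.10. The median of that list turned to 0.0777 after median centring.

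**Figure D4:**
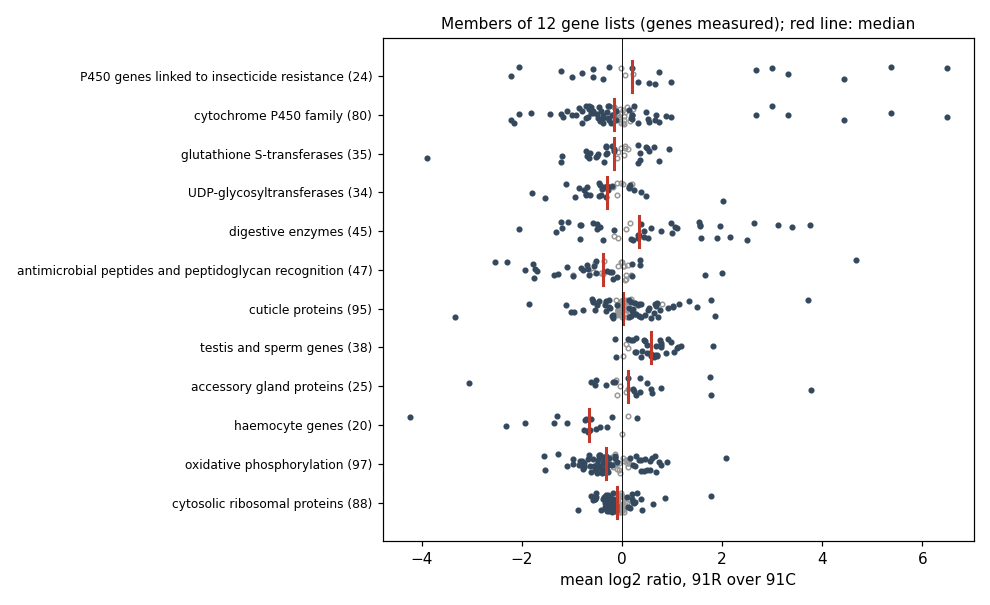
Mean log2 ratio of 91R over 91C for each member of 12 gene lists, 1 point per gene, filled where the gene was called, with the number measured in parentheses and the list median as a red line. The median is 0.576 for testis and sperm genes and -0.669 for haemocyte genes. That of oxidative phosphorylation, -0.319, turns to 0.0777 after median centring.

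Lists of other tissues, immunity and stress gave mixed directions. Digestive enzymes were higher in 27 of 45 genes and lower in 14, with 15 and 5 at least 2-fold apart (median 0.333, camera adjusted p = 0.0574). Their median was 0.713 after median centring, and the list passed in 3 of 16 other settings (lowest adjusted p = 0.0325). LysD was at 3.40 ± 0.15, LysB at 3.12 ± 0.10 and Jon99Ci at 2.63 ± 0.09, and LysB and LysD are close copies that one probe may not tell apart. Of 47 antimicrobial and peptidoglycan recognition genes, 7 were higher and 24 lower (median -0.374, adjusted p = 0.0574), with BomS3 at -1.73 ± 0.07 and PGRP-SC1b at 2.01 ± 0.12. The array medians of that list ranged from -0.582 to 0.0532, and it passed in 3 of 16 other settings (lowest adjusted p = 0.00157). Of 4 measured Turandot stress peptides, too few to test as a list, TotA was at -1.92 ± 0.66, TotC at -0.68 ± 0.63 (lost in 3 of 16 other settings, highest adjusted p = 0.075) and TotX at 1.38 ± 0.22. Of 26 heat shock genes, 7 were higher and 12 lower (median -0.253, or 0.0387 after median centring, adjusted p = 0.521), with Hsp60D at 1.79 ± 0.14, Hsp110 at -0.99 ± 0.12 and Hsp60C at 0.75 ± 0.03. Cuticle proteins were higher in 34 of 95 genes and lower in 22 (median 0.0215, or -0.0124 after median centring, adjusted p = 0.468), with Cpr62Bc at 3.71 ± 0.38, Lcp1 at 1.87 ± 0.15 and Cpr57A at -1.86 ± 0.09 by its brightest probe and at -0.10 and -0.45 by the others. Of 12 genes of cuticular hydrocarbon synthesis, 3 were higher and 3 lower (adjusted p = 0.902). Desat1 was at -0.91 ± 0.14, Baldspot at 0.42 ± 0.06 (n = 3) and mdy at -0.49 ± 0.11, with 0.14 as the mean of mdy's probes.

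Accessory gland genes were higher in 13 of 25 and lower in 7, or 13 and 8 adjusted over the list alone (median 0.12, camera adjusted p = 0.468). After median centring the median was 0.547 and the list passed (adjusted p = 0.00874), which it did in no other setting. Acp53C14c was at 3.77 ± 0.22, Met75Ca at 1.75 ± 0.11 and Dup99B, a ductus ejaculatorius peptide, at -3.06 ± 0.11. The accessory gland list shares 3 genes with the testis list. It also shares Acp65Aa, called higher at 1.78 ± 1.47 and counted above, with the cuticle protein list. Of 8 Y-linked genes 5 were higher and none lower (median 0.335, adjusted p = 0.167), with Ppr-Y at 0.52 ± 0.02, ARY at 0.39 ± 0.07 and kl-5 at 0.35 ± 0.02. Of 145 chemosensory genes 42 were higher and 30 lower, or 41 and 29 adjusted over the list alone (median 0.0105, or -0.113 after median centring, adjusted p = 0.776), with Gr43a at 1.95 ± 0.12, Obp73a at -0.84 ± 0.05 and Obp8a at 0.82 ± 0.04. Of 24 phototransduction genes 7 were higher and 7 lower (adjusted p = 0.834), with trpl at 1.00 ± 0.07, Rh3 at -0.78 ± 0.08 and Rh5 at -0.60 ± 0.03. Of 14 circadian clock genes 6 were higher and 6 lower (median 0.0284, adjusted p = 0.776), with Pdf, a clock neuropeptide, at 1.60 ± 0.04, cry at 1.36 ± 0.03 and to at -0.67 ± 0.07. Yolk and eggshell genes, which serve as a female marker, were higher in 5 of 15 and lower in 2 (adjusted p = 0.776), with Cp7Fb at 1.97 ± 0.17, Cp15 at 0.96 ± 0.17 and Cp16 at 0.28 ± 0.05, well above background on 3 of 4 arrays in 91R and 1 in 91C.

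The metabolic and housekeeping lists held single genes that stood apart. Of 22 muscle genes 5 were higher and 6 lower (adjusted p = 0.915), with TpnC25D at -0.85 ± 0.16, Mf at -0.26 ± 0.03 and tn at -0.24 ± 0.04, the last pair turning to 0.23 and 0.11 after median centring. The other probes of Mf gave 0.43, 0.24, 0.23, 0.06, 0.02 and -1.53. Of 18 fat body genes 5 were higher and 11 lower (median -0.269, or -0.0564 after median centring, adjusted p = 0.513), with Ilp6 at -1.23 ± 0.15 and Npc2g at 0.40 ± 0.03. Of 44 genes in the Malpighian tubule list 18 were higher and 11 lower (median 0.0418, camera adjusted p = 0.468). After median centring the median was 0.235 and the list passed. The list takes in every gene with a Vha symbol, so its members need not be particular to the tubule. Vha100-4 was at 3.39 ± 0.21, VhaAC39-2 at 2.76 ± 0.07 and Vha100-5 at -1.21 ± 0.12, all subunits of the proton pump. Vha100-4 was well above background in 91C on 3 of 4 arrays, and was at 6.98 with Agilent's processed signals. Of 20 glycolytic genes 4 were higher and 10 lower (median -0.162, or 0.25 after median centring, adjusted p = 0.568), with Pepck2 at -1.31 ± 0.20 and Ldh at -0.82 ± 0.07. Of 22 lipid storage genes 6 were higher and 7 lower (adjusted p = 0.776). Lsd-1 was 3.99-fold lower and Fatp1 at -0.63 ± 0.04, while AkhR, the receptor of the fat-mobilising hormone, was at 1.45 by its brightest probe and -0.83 by another. Of 88 cytosolic ribosomal protein genes 14 were higher and 43 lower (median -0.0981, or 0.358 after median centring, adjusted p = 0.0752, but 7.17e-06 after median centring and passing at a negative median in 3 more of 16 other settings), with RpS5b at 1.77 ± 0.07, RpL39 at -0.89 ± 0.06 and RpL10Aa at 0.85 ± 0.08. Of 44 proteasome genes 14 were higher and 16 lower (median -0.0279, camera adjusted p = 0.915). After median centring their median was 0.243 and the list passed as higher (camera adjusted p = 0.00678). Prosbeta2R1 was at 1.56 ± 0.09, Prosalpha5 at -1.34 ± 0.07 and Prosalpha4T1 at 1.02 ± 0.07. Counts adjusted over the list alone differed from those over all genes only for the 4 lists where they are given. Further medians after median centring were 0.405 for muscle, 0.347 for cuticular hydrocarbon, 0.16 for phototransduction, 0.0721 for clock, 0.05 for lipid storage and -0.091 for yolk genes, against 0.0182, 0.044, 0.0022, 0.0284, -0.0631 and -0.0168. The yolk median was also -0.235 with a normexp offset of 0, 0.166 with no background correction and 0.308 with Agilent's processed signals. With an offset of 0 the chemosensory median turned to -0.1 and the phototransduction median to -0.00136, and that of the proteasome was 0.000171 with the processed signals. A list of transposable elements had 0 members among the named probes. The mean and the median differ in sign for the P450 family, cuticular hydrocarbon, yolk, muscle, glycolytic and proteasome lists, and the test takes the sign of the median for the P450, glycolytic and proteasome lists.

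Probes of one gene did not always go the same way. Besides the genes whose other probes are given above, the probe farthest from the brightest gave 0.42 for cry, 0.32 for Cp7Fb, 0.26 for Hsp60C, 0.17 for Desat1, 0.14 for Ilp6 and loopin-1, 0.13 for kl-5, 0.04 for trpl, -0.13 for NimC2, -0.14 for nAChRalpha2, -0.22 for Gclc, -0.26 for Hsp110, -0.57 for ND5 and 1.41 for mdy. That probe gave 2.98 for Cyp4p1, 2.23 for Cyp6g1, 2.15 for Jhedup and -1.28 for Mdr50. For PPO2 it gave -1.91 and for Pepck2 -1.58. For the other named genes left out here it had the sign of the brightest. Of 3375 called genes with at least 2 kept probes, 2402 (71.2%, 95% exact Clopper-Pearson interval 69.6 to 72.7) had every probe on the side of the brightest, and of 232 such genes at least 2-fold apart 184 (79.3%) did. Among all 4801 genes with at least 2 kept probes, called or not, 3150 (65.6%) did. At the level of probes, 14833 of 26427 were called, 6688 higher and 8145 lower, and 1281 were at least 2-fold apart. Of the 6822 kept probes without a named gene, 2825 were called and 248 were at least 2-fold apart. Among 8873 probes spotted 2 times, the median SD between spots of one array was 0.0699 on the log2 scale, against 0.0933 between arrays.

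The size of large ratios and of dim genes depended on the processing. With Agilent's processed signals, named genes over 1.5-fold away from the values above, apart from those stated there and those given as bounds, were CG8708 (-8.225), CG31709 (6.70), Acp53C14c (6.69), CG33109 (6.53), CG9483 (6.26), Hex-t2 (6.23), Cpr62Bc (5.64), Cyp4p1 (5.435), VhaAC39-2 (4.88), Cp7Fb (4.25), Lcp1 (3.85), Gr43a (3.36), Prosbeta2R1 (2.54), Pdf (2.21), Cp16 (1.65), NimC2 (-2.19), Pepck2 (-2.80), Ugt302E1 (-2.86), CG11298 (-4.98), CG31832 (-5.19) and CG3397 (-5.85). With the mean of all probes such genes, besides Cyp4g1, mdy and those given as bounds, were Cyp4p1 (3.71), CG33109 (2.29), Cp7Fb (1.14), loopin-1 (0.55), AkhR (0.31), Cpr57A (-0.80), Hml (-0.95), CG17010 (-1.81) and CG3397 (-2.88).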

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

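The tests that exchanged the strains on some arrays, the adjustment for base composition and the tests of tissue shares were chosen only after results were seen. The bounds for the second-probe tests were written beforehand. Those tests were not in the planned design, and the patterns they address are themselves results. Over the 4 arrays, 148 named genes and gene lists were examined for an array far from the others, measured as its gap to the nearest array divided by the whole range, and 5 genes had one. Chance gives about 1 in 20 such cases, so 5 of 148 is no more than chance gives. For CG3397 the ratio was 0.917, with -4.72 on replicate 4 and -3.80 to -3.71 on the other arrays. For GstD11 it was 0.915, with -0.76 on replicate 1 and -0.69 on the other arrays. For Prx1 it was 0.915, with 0.51 on replicate 3 and 0.58 to 0.59 on the others. For NimC2 it was 0.907, with -1.55 on replicate 2 and -1.31 to -1.29 on the others. For Rh5 it was 0.881, with -0.56 on replicate 2 and -0.62 to -0.61 on the others.

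Most measured genes, 8703 of 12560, passed the threshold, and the majority differed by small ratios. A dye response set by the base composition of the probe is argued against, since the adjustment for base counts left the number of called genes at 1 times its value (8739 against 8703), and base composition explained 0.265% to 0.457% of the variance of the log2 ratios on the arrays. Effects of single probes stay open, since a second, non-overlapping probe had the same sign in a share of 0.736 of 2647 genes called under 2-fold, between the bounds set for the outcomes. Among all 4064 genes with such a probe, called or not, the sign was the same in 68.9%. A dye response shared by all probes of a transcript cannot be told apart from a difference between the strains, because 0 arrays had swapped dyes, and the strains' difference itself stays open beside it. Exchanging the strains on some arrays gives only 8 assignments, too few for a share under 0.05: 1 of them, the real one, called 8703 genes, and the highest of the others called 0. The arrays correlated at 0.902 to 0.925, so turning any of them over cancels the shared ratios, whatever their cause. The 0 was therefore to be foreseen and decides nothing.

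Genes at least 2-fold apart numbered 709, with 1 of the same 8 assignments giving as many (the real one), which are again too few for a share under 0.05, and 0 as the highest of the others. That 0 again follows from the correlation between the arrays and decides nothing. Among 95 genes higher in 91R with a second, non-overlapping probe, that probe reached an absolute log2 ratio of 0.5 in the same direction for a share of 0.474, so a sequence difference under a single probe may account for part of these genes. Among 87 genes lower in 91R the share was 0.598, which leaves the same explanation open. Probes of different transcripts of a gene would give such disagreement too. The second probe is always the dimmer one, and the normexp offset pulls the ratios of dim probes towards 0, which would also lower these shares. Neither was tested. By their brightest probe, 38 genes with a second probe were at least 4-fold apart, and in 14 of them (7 higher, 7 lower) the second probe lay within 0.5 of 0, Kap3 and CG17010 among them.

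Most testis and sperm genes were called higher and most haemocyte genes lower in 91R, though with an estimated correlation neither list passed (adjusted p = 0.906 for each). Of 35 measured testis genes outside the accessory gland list, a share of 0.0286 was lower at the threshold, with a median of 0.581 and quartiles of 0.28 and 0.774. Of 20 haemocyte genes a share of 0.05 was higher, with a median of -0.669 and quartiles of -1.14 and -0.407. The SD over genes was 0.396 for the testis set and 1.01 for the haemocyte set. Both shares repeat the counts that define the pattern, so they decide nothing on a larger share of testis RNA or fewer haemocytes in the 91R flies. Neither can be told apart from a different level of RNA per cell, nor from a dye effect, since no array had swapped dyes. A difference between the strains in the tissues themselves stays open and untested.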

How the results depend on the processing

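Only the adjustment for base composition was chosen after the data were seen; it gave 8739 called genes, 708 of them at least 2-fold apart. Over all other settings the count of called genes stayed between 7833 and 9719, within 1.5 times of 8703. Leaving out each array in turn gave 7833 to 8254 genes, 699 to 731 genes at least 2-fold apart, 12753 to 13497 probes and 4 to 7 gene lists past the threshold, 7 without replicate 3 and 5 without replicate 4. With Agilent's processed signals, and with the deposited value table that equals their ratio, 1263 genes were at least 2-fold apart, 707 of them among the 709, and a normexp offset of 0 gave 979. The number of gene lists past the threshold, 3, became 10 with median centring and 6 with no filter on dim probes, and the cause was not tested. With camera at an estimated correlation it was 0 (adjusted p = 0.906 for testis, haemocyte and oxidative phosphorylation genes). That correlation, estimated from only 4 arrays, was 0.19, 0.371 and 0.479 for these lists, against the preset 0.01 at which the 3 passed. Oxidative phosphorylation also lost the threshold with a normexp offset of 0 (-0.334) and with the processed signals and the value table (-0.311 each). The share of called genes whose probes all had one sign was 72.9% with probes well above background in both channels on all arrays, against 71.2%. Median centring reversed GstD1 (0.16), Mf (0.23), MRP (0.13) and tn (0.11), and the medians of oxidative phosphorylation (0.0777), cytosolic ribosomal proteins (0.358) and proteasome subunits (0.243). The mean of all probes reversed Cyp4g1 (-0.44) and mdy (0.14), whose probes disagree. The other reversals came from replacing loess, which depends on brightness, by median centring, the only step changed. Which scaling lies nearer the RNA levels was not tested. For named genes, 467 values without one array kept direction and side of the threshold, 7 lost the threshold and 2 gained it. Under other settings 1400 did, 6 lost it, 4 gained it and 6 reversed. For gene lists the values without one array were the same in 108 cases and passed in 8 more. Under other settings 327 were the same, 12 passed, 6 lost the threshold and 3 reversed. The slide as a random block was not run, because all arrays lay on 1 slide, and the separate-channel fit gave no value for the gene lists. No paired analysis was possible because there is only 1 group of arrays, and each ratio already sets the strains against each other within an array. Signal over background limits the dim genes: of the 709, 16 were not well above background in 91R and 20 not in 91C.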

Other observations

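The tests of proteasome copies and of mitochondrially encoded genes, and the choice of the Hsp70 and lysozyme genes, were made only after values were seen. For the tests of arms, neighbours and families the expected outcomes were written beforehand, but these tests were not in the planned design. Genes at least 2-fold apart were spread unevenly over the chromosome arms. On the X chromosome 54 of 1975 genes (2.73%) were at least 2-fold apart, against 6.14% of the genes on the other arms (Fisher's exact test, two-sided, adjusted p = 4.63e-10 over 6 arms). On 2R, the arm of Cyp6a2, Cyp6a8 and Cyp6g1, 181 of 2523 genes (7.17%) were, against 5.2% elsewhere (adjusted p = 0.000546), with 94 higher and 87 lower in 91R. The arms 2L (6.89%, adjusted p = 0.00714) and 3L (4.44%, adjusted p = 0.00754) also differed from the rest, while 3R (6.2%, adjusted p = 0.114) did not pass. After median centring the X held 2.89% against 7.19% elsewhere. Neighbouring genes also differed together: the Spearman correlation of log2 ratios across adjacent genes, pairs of the same symbol stem left out, was 0.0844 over 12335 genes. Genes named only by a CG or CR number have no stem, so pairs of them stayed in, whether or not they are copies of each other. The highest of 99999 permutations of gene order within arms was 0.0394 (permutation p = 1e-05, the smallest they can give), so the tests of arms, which treat genes as independent, give p-values that are too small. After median centring the correlation was 0.0753.

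Of 177 symbol families with at least 5 genes, 2 passed an adjusted p of 0.05 for holding more genes at least 2-fold apart than other genes (5.64% of all genes). In the Jonah serine proteases, gut digestive enzymes, 8 of 15 genes were at least 2-fold apart, 7 higher and 1 lower (Fisher's exact test, one-sided, adjusted p = 7.93e-05). In the cytochrome P450 family 15 of 80 were, 6 higher and 9 lower (adjusted p = 0.00307). The tests of families also treat genes as independent. Neighbours differed together, and hits such as Cyp12d1-d and Cyp12d1-p are near-identical copies, so these p-values are too small as well. The 4 measured Hsp70 genes were all lower in 91R, Hsp70Aa at -3.19, Hsp70Bbb at -2.94, Hsp70Bc at -2.40 and Hsp70Bb at -2.34. They are near-identical copies, so their probes are not independent. The lysozyme gene LysE was at 3.75, beside its copies LysD at 3.40 and LysB at 3.12.

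Several proteasome subunits have second gene copies whose symbols end in T or R, with or without a number, many of them known from the testis. Their median log2 ratio was 0.493 over 11 copies (10 higher, 1 lower), against -0.101 over 33 other subunits (4 higher, 15 lower). The medians differ by 0.595, and after median centring they were 0.588 and 0.155. The copies were looked at because a few of them stood out, so a test of that difference repeats the observation and decides nothing.

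Of 10 mitochondrially encoded genes in the oxidative phosphorylation list, 9 were lower in 91R and none higher, with a median of -0.419, against -0.284 over 87 nuclear genes of the list. ATP6, not among these 10, was called at least 2-fold lower. Median centring in place of loess moved the medians to -0.193 and 0.0806. Normalization that depends on brightness may account for the nuclear part. For the mitochondrial part it cannot be told apart from a lower RNA level, because the median stayed below 0 but above the bound of -0.3 set for a clear outcome.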
